A study of Mus musculus with 2 samples.

How the data were processed

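Total RNA over 200 nucleotides from 2 pools of mouse hindbrain at 10.5 days was sequenced, and per the labels RNA was extracted with the mirVana kit, 10 ng entered each library and spike-in RNAs were added. The labels list a manual of the SMARTer Ultra Low kit among the protocols; whether ribosomal RNA was removed and how the cDNA was primed are not given in the sources used here. The aligner and the quantification program are also not given in the sources used here. Assembly mm10 and annotation M4 are named in the deposited file notes.

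For each library a gene table and a transcript table were used. Per the file headers, each holds an expected count, that is an estimated count in which reads that fit several genes are divided between them. Per the file headers, TPM and a posterior mean TPM are given beside it; the deposited TPM of all rows, spike-ins included, has the same total in both libraries. FPKM is given per the file headers too. The transcript tables also hold, per the file headers, the percent of a gene's abundance in each isoform; the percent values in the text were recomputed from TPM. The effective length was the length minus 99 bases for all 129984 transcripts in both libraries, so short RNAs get high TPM from few counts and RNAs of 99 bases or less can get none. Spike-ins took 13.03% of TPM in replicate 1 and 7.82% in replicate 2, which by itself raises a gene's TPM in replicate 2 by 0.08 (log2).

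The gene table had 69691 rows, of which 43346 were annotated genes, 26248 predicted tRNAs and 97 spike-ins. Gene identifiers were matched without version to GENCODE M21 on the same assembly for symbols, classes and coordinates, and 42462 of 43346 (98.0%) matched. The 884 rows without a match held 0.27% and 0.26% of gene counts; they stayed in library sizes and were not named. Expected counts were rounded to whole numbers for the count model. Library sizes were the sums of these rounded counts in annotated genes, 38170078 and 36382223, without spike-ins and tRNAs. Intervals from counts cover counting error only, since reads are not independent molecules.

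With 1 group, no test between conditions was possible. The 8 contrasts compared the mean log2(TPM + 0.1), averaged over both libraries, of paired gene lists with a two-sided permutation test over genes (100000 resamples, or exact enumeration where fewer regroupings exist), adjusted by Benjamini-Hochberg over the 8, with a threshold of 0.05. A difference on this scale understates ratios of low genes. A gene in both lists of a contrast was left out of it. Replicate spread was estimated with edgeR 4.0.16 (R 4.3.3) from genes with a CPM (counts scaled to library size) of at least 1 in both libraries, TMM scaling and no covariates. Ratios between the pools were log2 ratios of TMM-scaled CPM with a prior count of 2. A list's median ratio was ranked among 10000 random lists of the same size matched on mean expression in 50 bins, and percentiles below 0.5 or above 99.5 were taken as beyond the limits; the percentiles describe these libraries and are not p-values. Of the 41 lists, the pair of adult beta globins was too small to rank, which leaves 40.

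Genes were named by rules set before the data were examined: members of the fixed lists, the 10 annotated genes of highest mean TPM, and the 10 highest and 10 lowest ratios between the pools among protein-coding nuclear genes with a mean TPM of at least 5. The closing section also names members of 2 lists, of early neuroepithelium and later radial glia, that were added after other values had been seen. Some list members are not reported here by name or in the figure of Hox genes. Detection meant a TPM of at least 1 in both libraries. Alternatives were the pseudocount, FPKM, posterior mean TPM, counts without length correction, medians, filters on low values, DESeq2 1.42.0 size factors, total count and spike-in scaling, other prior counts and each library left out. After the data were seen, ratios with the trends on GC content, gene length and expression removed (lowess in statsmodels 0.14.6, span 0.3) were added.

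The methods were tested on simulated data. Counts drawn with a biological coefficient of variation of 0.1, 0.2 and 0.4 gave estimates of 0.0987, 0.198 and 0.388 with no changed genes, and of 0.1345, 0.217 and 0.395 with 200 changed genes, which raise the estimate. Of 400 random lists of 12 genes with no shift, 8 fell beyond the percentile limits, and 400 of 400 did with a shift of 1 (log2). These lists were drawn from genes with many counts and independent noise. They say nothing about lists of low genes or of genes regulated together. The permutation test gave p under 0.05 in 7 of 200 runs with no difference and in 177 of 200 with a difference of 4 (log2) between lists of 26 genes in all. Smaller differences, such as those of the contrasts that did not pass the threshold, were not simulated. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alignments and signal tracks were not used here.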

Results

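Total RNA was sequenced from the hindbrain of mouse embryos of the B6NCrl strain at 10.5 days of development, with males and females pooled. The hindbrain is the part of the neural tube that forms the pons, the cerebellum and the medulla. The series held 1 group of 2 biological replicates, pools of 69 embryos (replicate 1) and 51 embryos (replicate 2), and each library was made from 10 ng of RNA with synthetic RNA spike-ins. The labels give both pools the same donor ID. They were treated as biological replicates because the labels number them so and give different embryo counts, and the SD and the spread between them describe these 2 pools only. The annotated genes received 38170090 expected counts in replicate 1 and 36382245 in replicate 2. A count in a transcript of 1 kb effective length was therefore worth 0.037 and 0.0413 TPM, the transcript abundance scaled to a fixed total per library. With a single group there was no comparison between conditions. The comparisons made were between gene lists within the libraries, fixed before the data were examined, and between the 2 pools. Values are the mean ± SD of the TPM of the 2 libraries (n = 2) unless the value of each library is given.

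The libraries had 14291 genes at a TPM of at least 1 in both, of which 12634 were protein-coding and 212 were long intergenic noncoding RNA genes. The median level of these genes was 16.4 TPM in replicate 1 and 17.1 TPM in replicate 2. The highest level was that of Hbb-y, an embryonic beta globin of red blood cells, at 6963 ± 516 TPM (chromosome 7, 103851749 to 103853216, mm10). It was followed by the tubulin Tuba1a (6169 ± 2279 TPM), the actin Actb (5773 ± 338 TPM), the histone Hist1h2ap (5366 ± 94.9 TPM) and the ferritin light chain Ftl1 (5346 ± 603 TPM). Next came the microRNA gene Gm22133 (5244 ± 9.79 TPM), the isomerase Ppia (4821 ± 413 TPM) and the mitochondrial ATP synthase subunit mt-Atp6 (4574 ± 602 TPM). Rn7s2 and Rn7s1, near-identical genes for the RNA of the signal recognition particle, were both at 4232 TPM, with SDs of 278.96 and 279.2. Their values are uncertain, since reads could be split between the copies. The value of Gm22133 is uncertain too: the gene lies inside Ftl1 on the same strand, at 45458089 to 45458197 of chromosome 7, and its effective length of 10 bases turned 1415 counts in replicate 1 into 5237 TPM. The 10 highest genes held 6.13% of the gene TPM in replicate 1 and 5.73% in replicate 2.

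Hox genes set position along the body axis. Each of the paralog groups 1 to 4 had at least 1 gene detected in both libraries. Group 4 was low in replicate 2, with a summed TPM of 1.85 against 31.68 in replicate 1. Most genes of the groups 5 to 13 were low or not detected. Hoxa2 was at 37.2 ± 13.99 TPM, Hoxb2 at 32.6 ± 10.0 TPM, Hoxd3 at 28.8 ± 22.3 TPM and Hoxb1, a gene of rhombomere 4 at this stage, at 15.8 ± 4.81 TPM. Of the 12 genes of groups 1 to 4, 7 reached a TPM of 1 in both libraries, and the lowest of these was Hoxa3 (5.41 ± 3.36 TPM). None of the 27 genes of groups 5 to 13 did so, and 22 of them were under 0.1 TPM in both. In group 4 only Hoxc4 reached a TPM of 1 in both libraries. Hoxa4, Hoxb4 and Hoxd4 were at 3.46, 2.5 and 2.06 TPM in replicate 1 and 0.11, 0.4 and 0.12 TPM in replicate 2. In replicate 1 they lay below Hoxc5 and Hoxb5 of group 5. Single genes thus showed no clear break between groups 4 and 5. Groups 1 to 4 had a mean log2(TPM + 0.1) 4.84 ± 0.79 above that of groups 5 to 13 (permutation test over genes, two-sided, p = 1e-05, the smallest that 100000 resamples can give; Benjamini-Hochberg adjusted p = 4e-05 over 8 contrasts). Genes are not independent replicates, here and in the 7 other contrasts. The exceptions in the posterior groups were Hoxc5, Hoxb5 and Hoxa5, at 8.5, 5.07 and 1.44 TPM in replicate 1 and 0.31, 0.11 and 0.02 TPM in replicate 2. Groups 11 and 12 had no count in either library; at this depth a count of 0 allows up to 3 counts.

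**Figure D1:**
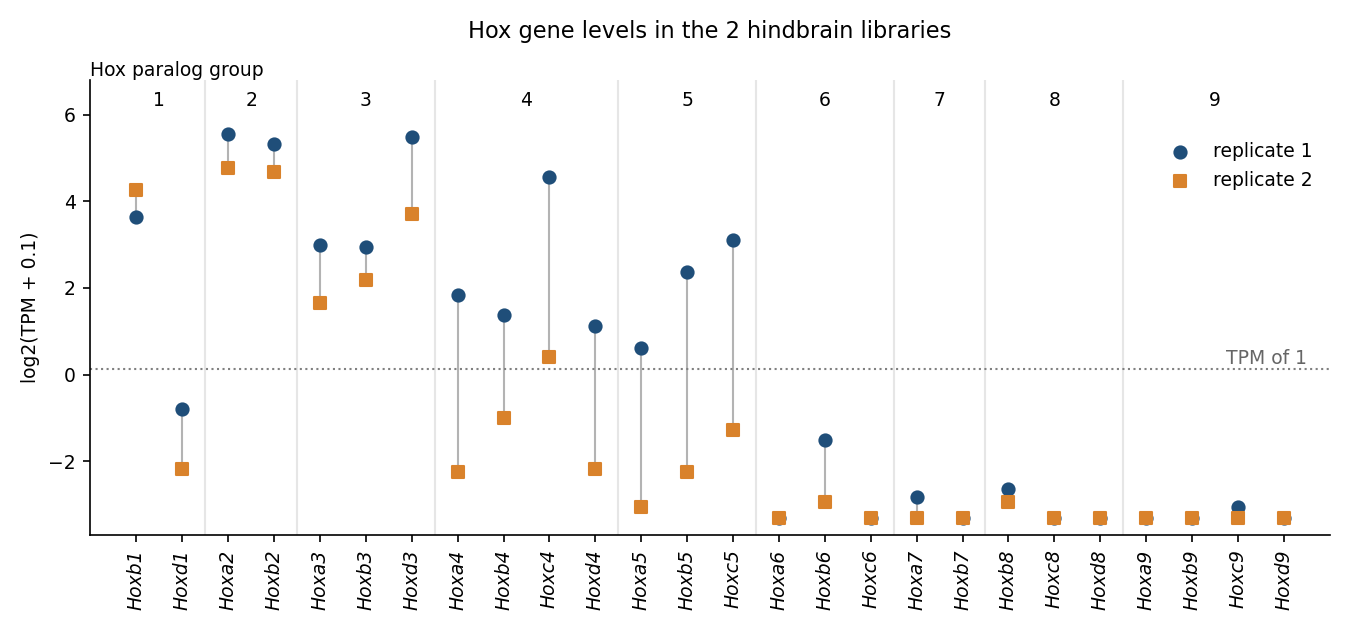
Hox genes of paralog groups 1 to 9 are placed along the x axis, and the y axis gives the level of each as log2(TPM + 0.1) in replicate 1 (circles) and replicate 2 (squares), joined by a line; the dotted line marks a TPM of 1. Each gene of groups 4 and 5 has a wider gap between the replicates than each gene of groups 1 to 3; Hoxc4 was at 23.7 TPM in replicate 1 and 1.22 TPM in replicate 2.

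Genes of hindbrain regions were higher than genes of the forebrain. The homeobox genes Irx2 and Irx3 were at 36.6 ± 5.78 and 35.7 ± 3.01 TPM. Gbx2, which acts on the hindbrain side of the isthmus, was at 28.1 ± 7.09 TPM. Of 15 hindbrain genes, 14 reached a TPM of 1 in both libraries. The exception was Egr2 (Krox20), at 0.45 TPM in replicate 1 and 1.72 TPM in replicate 2. Of 15 forebrain genes, 6 did, led by Lhx2 (17.9 ± 4.58 TPM), while Vax1 was at 0.145 ± 0.0778 TPM. The hindbrain list exceeded the forebrain list by 2.83 ± 0.74 in mean log2(TPM + 0.1), a 7.13-fold ratio of geometric means on that scale (permutation p = 0.0003, adjusted p = 0.0006). Some members of the forebrain list, such as Dlx1, Dlx2 and Lhx2, are also expressed in other tissue of the embryonic head.

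Genes of the midbrain and the isthmus lay between these lists. Otx2, a midbrain and forebrain factor, was at 13.8 ± 2.62 TPM, Fgf17 at 11.5 ± 3.53 TPM and Wnt1 at 11.3 ± 0.488 TPM, and 9 of 10 members were detected in both libraries; the exception was En2, at 0.570 ± 0.240 TPM. The difference between the hindbrain and the midbrain and isthmus lists, 1.19 ± 0.34 (log2), did not pass the threshold (permutation p = 0.0883, adjusted p = 0.118).

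Along the dorsoventral axis, 10 of 11 genes of the alar and roof plate and 11 of 11 genes of the basal and floor plate were detected in both libraries. The dorsal genes were led by Msx1 (164 ± 7.55 TPM) and Olig3 (74.99 ± 7.32 TPM), with Atoh1, the factor of the rhombic lip, at 28.1 ± 0.0141 TPM. The lowest detected in both was Pax7 at 2.02 ± 0.0990 TPM, and Gdf7 was under 1 TPM in replicate 2. The ventral genes were led by Spon1 of the floor plate (54.1 ± 12.2 TPM) and Nkx6-2 (29.4 ± 1.20 TPM), and the signal Shh itself was at 2.43 ± 0.0283 TPM. The dorsal list was 1.43 ± 0.06 (log2) above the ventral list, which did not pass the threshold (permutation p = 0.119, adjusted p = 0.136).

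Progenitor and neuronal genes were both abundant. Vim, the intermediate filament of neuroepithelial cells, was at 893 ± 50.4 TPM, Fabp7 at 561 ± 175 TPM and Hes5, a target of Notch signalling, at 465 ± 21.1 TPM. All 13 progenitor genes were detected in both libraries, down to Sox1 at 2.10 ± 0.120 TPM. Among 14 genes of postmitotic neurons, also all detected, the neuronal tubulin Tubb3 was at 600 ± 180 TPM, the neurofilament gene Nefl at 268 ± 59.1 TPM and the synaptic gene Syt1 at 7.77 ± 4.40 TPM. The progenitor list differed from the neuron list by -0.69 ± 0.52 (log2), which did not pass the threshold (permutation p = 0.446, adjusted p = 0.446); it was -1.06 in replicate 1 alone and -0.32 in replicate 2 alone. All 12 proneural and Notch ligand genes were detected, from Hes6 (280 ± 56.5 TPM) to Neurog3 (2.05 ± 0.877 TPM).

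Glial genes were low, and the neuron list exceeded the glial list by 6.40 ± 0.65 (log2; permutation p = 2e-05, adjusted p = 5.33e-05). Only 4 of 10 glial genes reached a TPM of 1 in both libraries. They were Cnp at 20.6 ± 3.45 TPM, Mbp at 12.6 ± 2.57 TPM, Aldh1l1 at 1.80 ± 0.622 TPM and Olig1 at 1.21 ± 0.106 TPM. The astrocyte genes Gfap and S100b were at 0.0800 ± 0.0990 and 0.0550 ± 0.00710 TPM.

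Genes of neuron subtypes were detected in part. Of 11 cranial motor neuron genes, 8 were detected in both libraries, from Isl1 (40.8 ± 18.1 TPM) to Phox2a (2.60 ± 1.32 TPM), and Mnx1 was at 0.0900 ± 0.0424 TPM. Of 17 interneuron transcription factors, 13 were detected, led by Dbx1 (47.2 ± 19.3 TPM). Of 11 serotonergic and noradrenergic genes, 7 were detected, with Gata3 at 12.8 ± 1.99 TPM and Dbh, the enzyme that makes noradrenaline, at 3.74 ± 0.198 TPM, while Tph2, which starts serotonin synthesis in neurons, was at 0.0800 ± 0.0707 TPM. Of 8 transmitter genes, 4 were detected, with the glutamate transporter Slc17a6 at 8.24 ± 4.77 TPM and Gad1, which makes GABA, at 4.04 ± 3.56 TPM.

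RNA of cells from outside the neural tube was present. The 5 embryonic and adult alpha and beta-like globins of the red blood cell list were between 2071 (Hba-a1, SD 18.1) and 6963 TPM (Hbb-y). Hba-a1 and Hba-a2 are near-identical copies, so the split between them is uncertain. All 10 endothelial genes were detected, from Egfl7 (73.8 ± 15.8 TPM) to Tek (7.23 ± 0.283 TPM), as were all 12 mesenchymal genes, from Col3a1 (312 ± 1.12 TPM) to Tbx15 (1.86 ± 0.120 TPM). Of 10 macrophage and microglia genes, 9 were detected, with C1qb at 25.2 ± 7.71 TPM and Cx3cr1 at 5.92 ± 0.863 TPM. The endothelial list exceeded the macrophage list by 1.15 ± 0.57 (log2; permutation p = 0.0255, adjusted p = 0.0408). That call rested on replicate 2: in replicate 1 alone the difference was 0.75 (permutation, adjusted p = 0.157), and in medians it was 0.92 (adjusted p = 0.102). Krt8 and Krt18, keratins of surface ectoderm, were at 44.3 ± 9.55 and 39.0 ± 10.4 TPM, and 7 of 8 members of that list were detected, the lowest being Krt14 (1.40 ± 0.184 TPM). Of 10 muscle and heart genes, 2 were detected in both libraries (Actc1 at 9.48 ± 6.29 TPM and Myl7 at 7.23 ± 7.24 TPM).

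**Figure D2:**
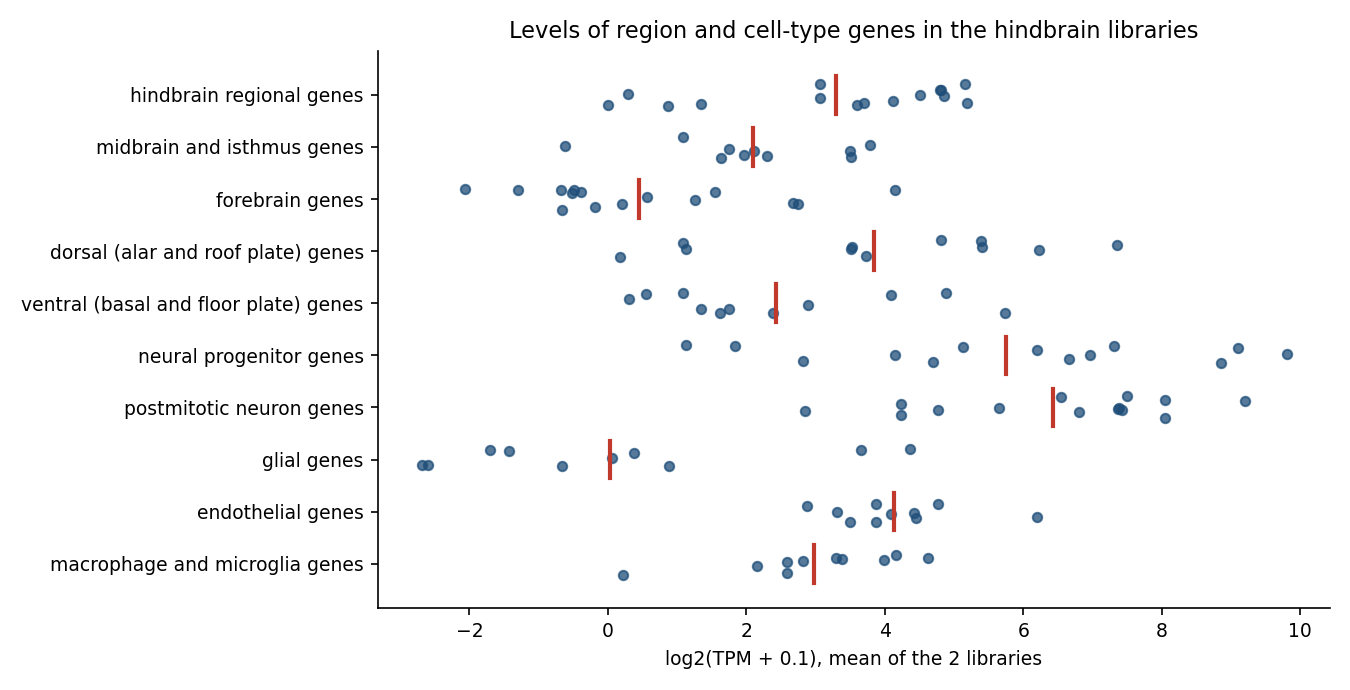
Each point is a gene of a fixed list, the x axis gives its log2(TPM + 0.1) averaged over the 2 libraries, and the red bars mark the list means; points are spread vertically at random within a list. The mean of the hindbrain list (3.29) lies above that of the forebrain list (0.46), and the neuron list (6.43) lies above the glial list (0.03).

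Most counts in the annotated rows came from protein-coding genes, although total RNA was the input. Reads outside these rows are not covered by the shares, so the content of ribosomal RNA is not known here. Protein-coding genes held 91.2 ± 1.67% of expected counts, spike-ins 4.72 ± 1.79%, long noncoding genes 1.66 ± 0.116%, pseudogenes 1.26 ± 0.113%, mitochondrial genes 0.830 ± 0.120% and small noncoding genes 0.122 ± 0.00485% (SD, n = 2). Of TPM, which weights short RNAs more, protein-coding genes held 79.98 ± 3.001% and spike-ins 10.4 ± 3.68%. Histone genes whose transcripts carry a poly(A) tail were 7.09 ± 0.06 (log2) above replication-dependent histone genes, whose transcripts end in a stem-loop (permutation p = 1e-05, the smallest possible; adjusted p = 4e-05). All 9 polyadenylated histone genes were detected, from H2afz (2583 ± 141 TPM) to H2afy2 (255 ± 6.43 TPM). Of 64 replication-dependent genes 48 were, with Hist1h2ap far above the others; the next was Hist1h4d at 297 ± 22.6 TPM. Replication-dependent histone genes form families of similar copies, so their individual values are uncertain, and the contrast weighs each copy alike. Summed over each list, TPM in replicates 1 and 2 was 8995 and 8845 for polyadenylated genes and 6521 and 6675 for replication-dependent genes. Hist1h2ap alone made up 5299 and 5433 TPM of the latter sums. Among small RNAs without a tail, Rn7sk was at 105 ± 10.8 TPM, Rpph1 at 35.3 ± 5.98 TPM and Rmrp at 2.41 ± 0.163 TPM, all far below Rn7s1 and Rn7s2, which lack a tail too.

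The 2 libraries were compared with each other gene by gene. Across 15006 genes with a mean TPM of at least 1, their log2(TPM + 0.1) had a Pearson r of 0.951 and a Spearman rho of 0.975; this is across genes, which are not independent replicates. The biological coefficient of variation, the spread between pools beyond counting error, was 0.204 over 14385 genes. It was 0.262 at a log2 CPM of 0, 0.272 at 3, 0.154 at 6 and 0.145 at 9. The spike-ins, which were added and not dissected, had a coefficient of 0.0442 over 54 sequences. Of 10262 protein-coding nuclear genes with a mean TPM of at least 5, 97.2% differed by less than 2-fold between the pools. There were 248 at least 2-fold higher in replicate 1 and 44 at least 2-fold higher in replicate 2. These ratios are relative to the typical gene of each library. When spike-ins set the scale, the median of all detected genes moved by 0.82 (log2) towards replicate 2, and the counts became 32 and 2562. With 1 library on each side these differences have no replicate check and no p-value, and they describe these libraries only.

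In summed counts, Hox groups 3 to 5 differed between the pools by more than groups 1 and 2. The fold of replicate 1 over replicate 2 in summed counts was 0.775 for paralog group 1, 1.73 for group 2, 3.07 for group 3, 17.2 for group 4 and 49.9 for group 5, which had 843 counts in replicate 1 and 16 in replicate 2. Single genes did not all keep this order: Hoxb3 of group 3 had a log2 of replicate 2 over replicate 1 of -0.78, against -0.86 for Hoxa2. In group 1 Hoxb1 was higher in replicate 2 (0.49), while Hoxd1, with 23 and 5 counts, was at -1.77. Hoxc4 (chromosome 15, 103018934 to 103036852) had the lowest ratio of the protein-coding genes ranked (-4.31). Hoxd3 (-1.88) and Hoxd4 (-3.74) overlap in the annotation, so the split of counts between them is uncertain. The annotated span of Hoxa3 likewise covers Hoxa4 and Hoxa5, and that of Hoxc5 covers Hoxc6, so the group sums carry this limit too. The list of groups 1 to 4 had a median of -1.60, below all of 10000 random lists of the same size matched on mean expression (percentile of 0). Under spike-in scaling its median was still below 0, at -0.83.

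Neuronal genes were lower in replicate 2 relative to the typical gene. All 14 genes of postmitotic neurons had a ratio below 1, with a median log2 of -0.86 (percentile of 0 among random lists); Tubb3 was at 727 and 473 TPM, and the filament gene Ina at 197 and 63.0 TPM, in replicates 1 and 2. The proneural list had a median of -0.54 (percentile 0.01), in which 4 of 12 genes went the other way, among them Neurod1 at 16.7 TPM in replicate 1 and 44.6 TPM in replicate 2. The transmitter list stood at -1.91 (percentile of 0; Gad2 at 10.7 and 1.02 TPM), the interneuron factors at -0.93 (percentile of 0; Lhx1 at 24.5 and 8.27 TPM, but 4 of 17 higher in replicate 2, among them Dbx1 at 33.6 and 60.8 TPM) and the cranial motor neuron genes at -0.79 (percentile 0.02; Slc18a3, the vesicular acetylcholine transporter, at 9.58 and 2.37 TPM, but 2 of 11 higher, among them Isl1 at 28.1 and 53.6 TPM). In the transmitter list 7 of 8 genes were lower. The serotonergic and noradrenergic list stood at -0.71 (percentile 0.1), but among its 7 members with a mean TPM of at least 1 the median was 0.072. Splicing regulators had a median of -0.34 (percentile of 0), with Rbfox1 at 9.17 and 4.04 TPM, and 9 of 13 were lower. Under spike-in scaling the median of the neuron list was -0.04 and those of the proneural list and the splicing regulators were 0.28 and 0.48.

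Cell cycle genes went the other way. All 16 were higher in replicate 2, with a median log2 of 0.37 (percentile of 100), Top2a at 179 and 269 TPM and the proliferation gene Mki67 at 21.8 and 37.8 TPM. All 7 RNA-binding and chromatin genes of early embryos were higher in replicate 2 (median 0.70, percentile of 100), among them Lin28a at 10.6 and 23.2 TPM and Lin28b at 8.58 and 25.4 TPM. The progenitor list was within the limits of 0.5 and 99.5 (median -0.16, percentile 2.6).

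Lists of other cell types moved in different directions. The choroid plexus list was lower in replicate 2 (median -0.98, percentile 0.08), with Ttr, the transthyretin of choroid plexus epithelium, at 249.8 and 35.3 TPM and Kcne2 at 10.5 and 1.14 TPM. All 10 macrophage genes were lower in replicate 2 (median -0.71, percentile 0.17). The ganglion and placode list was higher (median 0.72, percentile of 100), with Oc90, an inner ear gene, at 13.2 and 45.1 TPM. The muscle and heart list (median 0.98, percentile of 100) held Myl7, an atrial myosin light chain, at 2.11 and 12.4 TPM, but its members were low (list medians of 0.275 and 1.3 TPM) and 3 of 10 were lower in replicate 2, among them Myf5 at 3.47 and 0.94 TPM. In the ganglion and placode list 2 of 10 were lower. The forebrain list (median 0.98, percentile of 100) and the neural crest list (median 0.54, percentile 99.99) were also higher in replicate 2, with 5 of 15 and 3 of 8 genes lower, but members with a mean TPM of at least 1 had medians of 0.18 (percentile 90.8) and 0.16 (percentile 88.7). The endothelial (0.03), red blood cell (0.07) and mesenchymal (-0.17) medians were within the limits. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were higher in replicate 2, and the list they share with Xist had a median of 0.47 (percentile of 100): Ddx3y was at 8.88 and 15.4 TPM, and Xist, the RNA of the inactive X chromosome, at 10.1 and 11.4 TPM. In all, 17 of 40 lists lay beyond the limits, 10 of them lower and 7 higher in replicate 2. Of the 10, 4 had a median above 0 under spike-in scaling, which moves every gene by about the same amount.

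**Figure D3:**
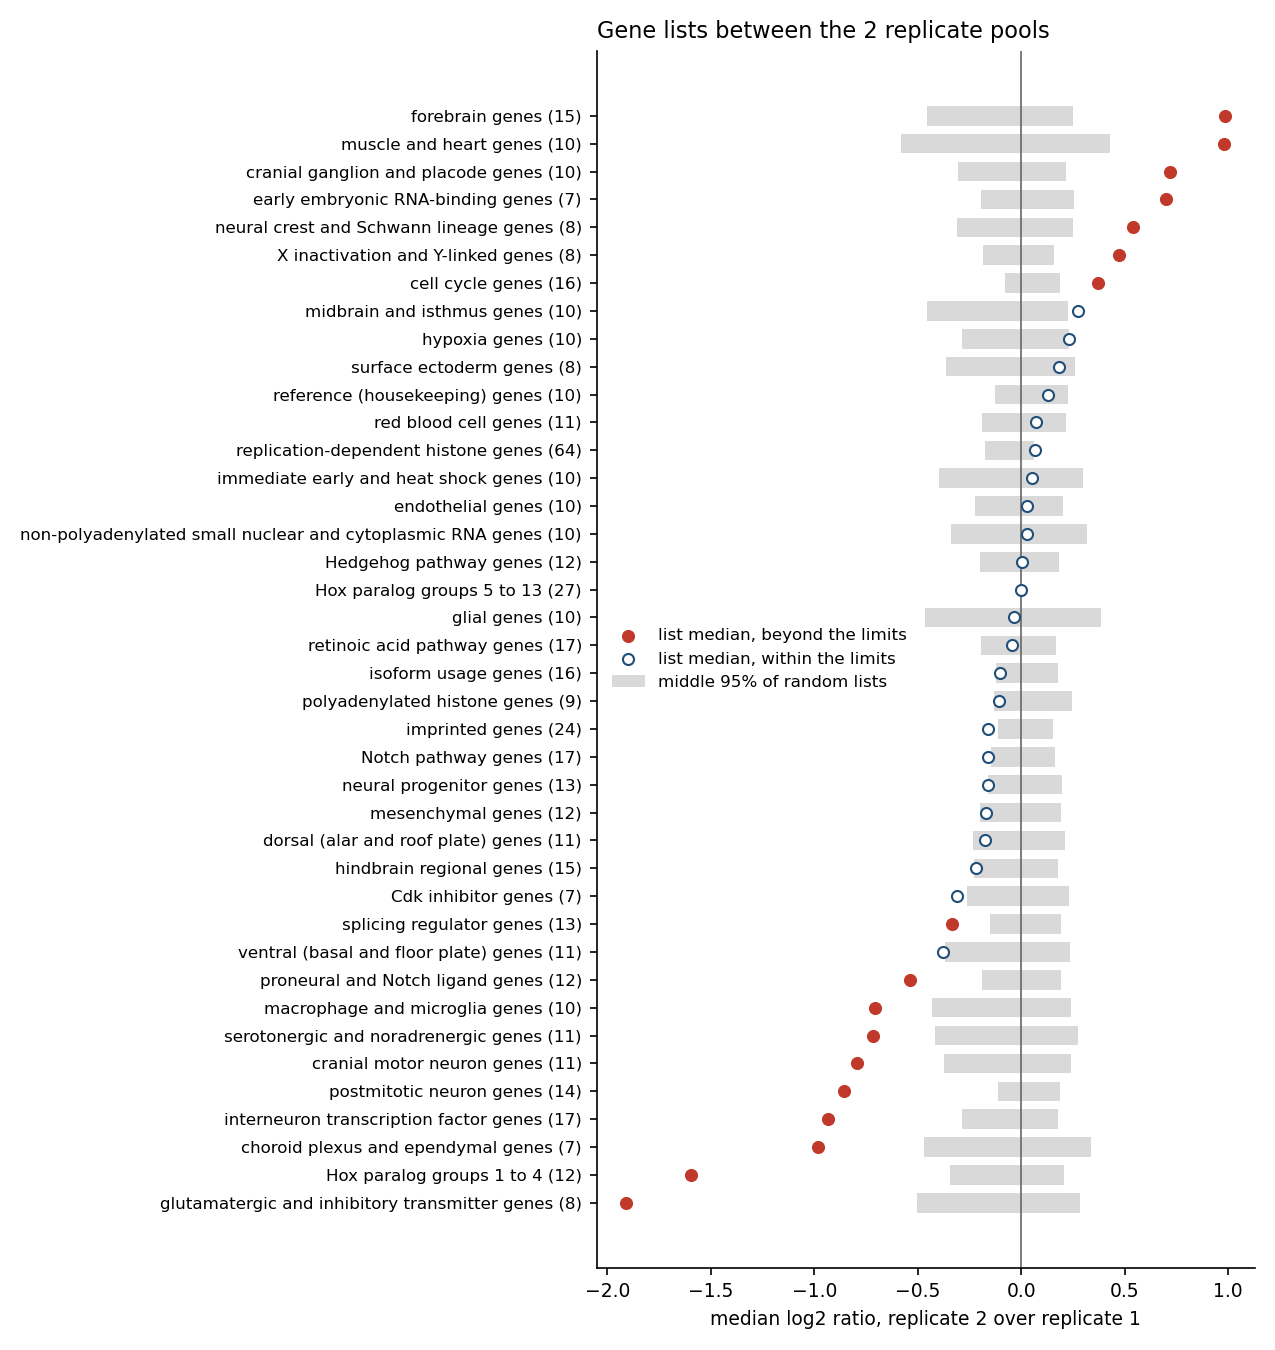
Each row is a fixed gene list with its number of genes, and the x axis gives the median log2 ratio of replicate 2 over replicate 1; gray bars span the middle 95% of 10000 random lists matched on expression, and filled points lie below percentile 0.5 or above 99.5. The transmitter list (-1.91) and the Hox list of groups 1 to 4 (-1.60) lie farthest to the left, and the forebrain and the muscle and heart lists (both 0.98) farthest to the right.

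Among single genes, the lowest ratios after Hoxc4 belonged to Kcne2 (-3.22), Defb11 (-3.19), Tmem130 (-3.10), Gad2 (-2.91), Ttr (-2.90), Lamp5 (-2.87), Pcp4 (-2.57), Robo3 (-2.39), a receptor of commissural axons, and Pcsk1n (-2.35); Gad2, Ttr and Kcne2 are list members. The highest were those of Gm3055 (4.07), Myl7 (2.39), Wfikkn1 (2.20), Gm10273 (2.10), Dlx5 (2.05), Oc90 (1.75), Gm7271 (1.71), Actn3 (1.61), Fgf8 (1.60), the signal of the isthmus, and Ap1m2 (1.60). Defb11 rested on 65.3 and 5 counts and Gm3055 on 9.21 and 174 counts in replicates 1 and 2.

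In the transcript table, 8 of 16 genes chosen for their known isoforms had a most abundant isoform with over 50% of the gene's TPM. The pyruvate kinase gene Pkm gave 92.8 ± 4.81% of its TPM to Pkm-201 and 7.24 ± 4.81% to Pkm-202 (SD, n = 2). Cdc42-202 held 90.6 ± 4.03%, Gnas-208 84.0 ± 0.612%, Gli2-201 88.9 ± 8.39%, Ncam1-204 75.2 ± 5.04%, Hoxa3-201 96.6 ± 1.55% and Hoxb3-202 69.4 ± 1.30%. Ptbp2 had a single annotated isoform. Among the rest, Fgfr1-202 held 43.1 ± 0.310% and Ptbp1-206 38.3 ± 0.148%. Mapt-205 had 48.8% in replicate 1 and 28.8% in replicate 2, where Mapt-204 was the first with 30.3%. Meis2-206 had 25.3% and 12.9%, and in replicate 2 Meis2-201 was the first with 19.5%. The SD across pools covers no uncertainty in assigning reads to isoforms.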

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

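Predicted tRNA genes, which no comparison used, received 38 expected counts in replicate 1 and 30.76 in replicate 2, summed over all their rows. The limit of 3 counts for a count of 0 holds for a single row and does not apply to these sums. The counts fell in 9 of 26248 rows, and 63 rows were longer than the 99 bases that the effective length removes, so shorter tRNA rows could not receive a count. No explanation was tested for this signal.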

How the results depend on the processing

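Of 64 alternatives to the 8 contrasts, 62 kept the direction and the side of the threshold; both exceptions belonged to the endothelial and macrophage contrast, whose difference was 0.92 in medians and between 0.75 and 1.55 when either library was left out, but 2.29 (adjusted p = 0.0001) in counts without length correction. The Hox contrast kept its side but fell from 4.84 to 2.48 with a pseudocount of 1 and to 2.96 (adjusted p = 0.0384) for members with a mean TPM of at least 0.1. The progenitor and neuron contrast was between -1.06 and -0.32 when either library was left out. FPKM is proportional to TPM within a library, so that alternative could differ only through the pseudocount. The cause of the changes in the endothelial and macrophage contrast was not tested, and the macrophage list itself was lower in replicate 2. Genes detected in both libraries ranged from 10492 (TPM of at least 5) to 19476 (TPM of at least 0.1). The biological coefficient of variation was 0.416 with spike-in scaling, 0.241 with no filter on low counts and 0.184 for a mean TPM of at least 5. With spike-in scaling 2594 genes differed at least 2-fold, 32 higher in replicate 1 and 2562 in replicate 2, because that scaling moves the median gene by 0.82 (log2); under the other planned scalings and prior counts the total was between 293 and 298. With the trends on GC content, length and expression removed, a setting chosen after seeing the data, it was 275. The protein-coding share was 79.98% of TPM. The correlation across genes was 0.984 over all genes, 0.972 for a mean TPM of at least 10 and 0.975 with a pseudocount of 1.

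All 17 gene lists beyond the limits were also beyond them, in the same direction, with the ratio of TPM and with DESeq2 size factors. Size factors move a list and its random lists by about the same amount, so the DESeq2 setting could hardly have differed. The ratio of TPM rests on the same counts, with the same transcript lengths in both libraries, so it is no independent check either. Members with a mean TPM of at least 1 kept 14 of the 17 and brought 1 more list beyond the limits, the imprinted genes (percentile 0.37). The forebrain and neural crest lists came within the limits, and the median of the serotonergic and noradrenergic list changed sign to 0.072, since its low members carried the ratio. The trend removal kept 15 of the 17 among 38 lists with enough values; the serotonergic and noradrenergic list came within the limits, and the list of Y-linked genes and Xist had too few values. It also brought 3 lists beyond the limits, the imprinted genes (percentile 0.08), the hypoxia genes (99.6) and the replication-dependent histone genes (99.8), for a total of 18. Isoform counts over 50% were 8 or 9 under every alternative run, while 8 of 16 shares moved by more than the SD with expected counts. With posterior mean TPM 8 of 16 did so too. With expected counts the share of Mapt-205 was 23.0% instead of 38.8%, and that of Numb-204 was 54.4% instead of 39.0%. Leaving out a library moves a mean of 2 values by less than their SD by construction, so it says nothing about the stability of levels and shares. Replicate spread and ratios between the pools cannot be computed without either library. No paired analysis was possible because the series has a single group. Depth limits the genes under about 0.1 TPM, where 3 counts at 1 kb are as large as the value.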

Other observations

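Imprinted genes were among the abundant ones, and 22 of 24 were detected in both libraries. Nnat was at 1729 ± 651 TPM, Mest at 1218 ± 264 TPM, Grb10 at 395 ± 95.01 TPM, the growth factor Igf2 at 190 ± 8.87 TPM and H19 at 109 ± 14.8 TPM (mean ± SD, n = 2). The list's median between the pools was just inside the limits (-0.16, percentile 0.51). It was beyond them among members with a mean TPM of at least 1 (percentile 0.37) and with the trends on GC content, length and expression removed (0.08), and within them with the ratio of TPM (3.04). Of the 24 genes, 14 were lower and 10 higher in replicate 2. Among the lower ones, Meg3 was at 310.04 TPM in replicate 1 and 153 TPM in replicate 2, Ndn at 359 and 195 TPM. In the retinoic acid list, 15 of 17 genes were detected, led by the binding proteins Crabp1 (1553 ± 31.4 TPM) and Crabp2 (832 ± 35.4 TPM). The degrading enzymes Cyp26a1 and Cyp26b1 were at 30.1 ± 0.863 and 17.5 ± 3.33 TPM, and the synthesis enzymes differed between the pools, with Aldh1a2 at 4.58 and 0.67 TPM and Aldh1a3 at 1.34 and 3.86 TPM in replicates 1 and 2. All 12 Hedgehog pathway genes (median ratio 0.01) and all 17 Notch pathway genes (-0.16) were detected, from Gas1 (72.1 ± 7.92 TPM) and Hes5 downwards, and both lists were within the limits.

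The Cdk inhibitor Cdkn1c, a gene of cells leaving the cycle, was at 393 TPM in replicate 1 and 262 TPM in replicate 2, and Cdkn2a had a TPM of 0 in both. Of the 7 Cdk inhibitor genes, 4 were lower and 2 higher in replicate 2, and the list was within the limits (median -0.31, percentile 1.51). Of 10 hypoxia and glycolysis genes 9 were detected, with Ldha at 1759 and 2884 TPM and Slc2a1 at 132 and 205 TPM (list median 0.23, percentile 97.3, or 99.6 with the trends removed). Of 10 immediate early and heat shock genes 7 were detected, from the heat shock gene Dnajb1 (85.4 ± 12.6 TPM) and Ier2 (75.9 ± 5.69 TPM) down to Fos (1.22 ± 0.0212 TPM), and their list did not stand apart (0.05, percentile 64.4); neither did the 10 reference genes (0.13, percentile 81.2). The adult beta globins Hbb-bs and Hbb-bt made up 3.84% of beta-like globin TPM in replicate 1 and 1.86% in replicate 2, while Hbb-bh1, an early embryonic form, was 43.1% and 52.5% of the level of Hbb-y; these globins are similar in sequence and the split of reads between them is uncertain. The SD of the log2 ratio over spike-ins was 0.21, against 0.48 in genes of the same counts (95% of draws between 0.33 and 0.77).

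In the hypotheses that follow, the counting interval, the ratio by Hox paralog group and the comparisons of the endothelial with the macrophage list and of the progenitor with the neuron list were chosen after their values had been seen. The others were set down before. The labels give the pools no difference besides their number of embryos, so no biological explanation from the design was tested.

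Hox genes of groups 4 and 5 were far lower in replicate 2. Noise in counting reads is argued against: their summed counts, 2440 and 104, gave a ratio of 22.2 after scaling (exact 95% interval 18.3 to 27.3). The interval treats reads as independent molecules, which they are not, so noise in the sampling of molecules is not excluded by it. Bias by GC content, length or expression is argued against, since the median log2 ratio of the 9 genes of groups 3 to 5 with a mean TPM of at least 1 went from -3.74 only to -3.65 when these trends were removed. A candidate explanation is that the pool of replicate 1 included tissue from farther back, near the border with the spinal cord; the fold of replicate 1 over 2 in summed counts rose at all 4 steps from paralog group 1 to group 5, which is what such a difference in dissection needs. The first of these steps rests on Hoxb1, which held most counts of group 1. It stays a hypothesis, since the same values raised it.

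Neuronal genes were lower, and cell cycle genes higher, in replicate 2; removing the trends on GC content, length and expression left the neuron list at -0.96 (middle 95% of random lists from -0.14) and the cell cycle list at 0.27 (up to 0.13), so those trends are not the whole cause. For a lower share of the neural tube that raises all other cell types alike, the endothelial and macrophage lists were compared. Their medians of 0.03 and -0.71 (SD of members 0.19 and 0.29) differed by 0.74, so these lists did not move alike. The macrophage list also holds genes of microglia, which can lie within the neural tube, so this comparison cannot decide the matter. Tissue from outside the neural tube is argued against as the whole cause of the fall in neuronal genes. It would dilute progenitor genes alike, while the progenitor median of -0.16 (SD of members 0.24) was 0.69 above the neuron median of -0.86 (SD 0.47). Some progenitor genes, such as Vim, are also expressed outside the neural tube. More of certain outside tissue in the pool of replicate 2, as a part of the cause, stays open, as does its part in the rise of cell cycle genes: the placode (0.72) and the muscle and heart (0.98) lists were above their random lists, and the crest list (0.54) was too, though not among its members with a mean TPM of at least 1 (0.16). An earlier mean stage of the pool of replicate 2 may account for the pattern, for which 14 genes of early neuroepithelium and 14 of later radial glia were listed before their ratios were looked at. The 5 early genes with a mean TPM of at least 1, such as Sall4 (15.1 and 37.4 TPM), had a median of 0.70. The 12 later ones, such as Nfib (13.8 and 6.95 TPM), had a median of -0.64, a difference of 1.34 where more than 0.3 was predicted. Early genes ranged from 0.22 (Mycn) to 1.25 (Sall4) and later genes from -1.48 (Tnc) to 0.51 (Aldoc). Of the later genes, Aldoc and Slc1a3 (0.03) were not lower in replicate 2. The progenitor list, which was not part of this prediction, was not higher in replicate 2. Of its 13 genes, 10 were lower there (median -0.16, percentile 2.6, within the limits). A different rostrocaudal extent of the dissection was not tested as a cause of this pattern and stays open.

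Whether the cDNA was primed from poly(A) tails only could not be decided. The prediction was that Rn7sk, Rmrp and Rpph1, which lack a tail, would each lie below the median TPM of detected genes if so, and that at least 2 would exceed the 90th percentile (115 and 121 TPM) if not. In the data 2 of the 3 exceeded the median in both libraries and 0 exceeded the 90th percentile in both. The other part of the prediction for priming from tails, replication-dependent histone genes at least 4 (log2) below the polyadenylated ones, was met with a difference of 7.09. That difference is a mean over genes, and reads are divided between similar copies of the replication-dependent genes. In summed TPM the lists lay closer, at 8995 and 8845 against 6521 and 6675 in replicates 1 and 2. Most of the latter sums came from Hist1h2ap alone, at 5299 and 5433 TPM, a value that is uncertain. This part was met but cannot decide the question alone, since the prediction also needed Rn7sk, Rmrp and Rpph1 below the median. Rn7s1 and Rn7s2, which lack a tail and were not part of the prediction, were both at 4232 TPM, far above that 90th percentile. Their short effective length of 201 bases gives a high TPM per count, and their level cannot decide the question either. The amount of these RNAs in the cells is not known here, so the share captured could not be computed. Priming inside transcripts at runs of A was not tested.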
